A study of Drosophila melanogaster with 3 samples.

How the data were processed

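The data were peak lists from chromatin immunoprecipitation and sequencing of 3 biological replicates, with 1 technical replicate each, of transgenic Drosophila embryos (0 to 24 h, mixed sex, whole organisms) expressing Ets65A with a C-terminal GFP. The labels give sonication, fragments of 200 to 800 bp and an anti-GFP antibody, while the antibody field names Ets65A; the precipitation is described here as one of the GFP fusion. The authors made a list per replicate against a control, a list from the pooled alignments of the 3 replicates against a control, and a list of peaks passing an IDR threshold that was derived from these, in the dm6 and the dm3 build. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak in the deposited lists carried a signal value (a score whose scale is not stated) and a q-value as -log10 q, and all signal values printed are the authors'. The deposited q-values reached a ceiling in each list, shared by 2533 of the 2780 dm6 IDR peaks, so peaks were ranked by signal value. The lowest -log10 q was 3.23 in the dm6 IDR list but 0.0177 in the pooled list and 0.0728, 0.101 and 0.179 in those of replicates 1, 2 and 3. The pooled and replicate lists therefore include calls with little evidence of enrichment. Replicate lists ended at 30000 peaks. Peak lists hold no read counts, so the depth per sample is unknown, and the intervals given for shares and rates cover counting error over peaks or genes only. Signal tracks, alignments and the control were not analysed here.

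Choices were fixed before the data were examined, except where a test or alternative is said to be chosen after seeing the data. The samples form 1 group, so no test compared groups of samples; p-values are over peaks, positions or genes, which are not replicates, and agreement between replicates is given separately. Annotation and sequence were those of Ensembl release 115 (BDGP6.54, the dm6 sequence), restricted to arms X, 2L, 2R, 3L, 3R and 4. Each peak was placed by its summit in the first class that applied among promoter (within 500 bp of a TSS of a protein-coding gene), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic, and compared with 10000 sets of random positions that kept the number per arm. dm3 and dm6 positions were never converted into each other.

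For 18 fixed motifs and for every 6-mer, the presence on either strand within 100 bp of the summit was compared with 1 flank window of equal size per peak, centred 500 bp away on a side drawn at random, by the exact McNemar test, two-sided. A gene counted as bound when an IDR summit lay within 500 bp of any of its TSSs. Bound genes were compared for 21 fixed gene lists with all other of 13945 protein-coding genes by Fisher's exact test, two-sided. The lists were the ETS family, pan-neuronal, neuroblast, glia, axon guidance, mesoderm and muscle, hemocyte and blood, trachea, epidermis and cuticle, endoderm and gut, germ line, segmentation, Hox, EGFR and FGF signalling, Notch signalling, ecdysone response, cell cycle and replication, cytoplasmic ribosomal proteins, oxidative phosphorylation, proteasome subunits and RNA splicing. All symbols were found in the annotation, after synonyms were merged, except 1 of 11 in the endoderm and gut list. P-values were adjusted by Benjamini-Hochberg within classes, motifs, 6-mers and lists, at a threshold of 0.05. Overlap of the 2780 strongest peaks of each replicate (at least 1 bp) was compared with 100 circular shifts along each arm, median signal with 100000 permutations, and arm counts with a chi-square test.

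Named genes followed a rule: the 25 protein-coding genes with the strongest IDR peak within 500 bp of a TSS that was among the strongest of all 3 replicates, every ETS family gene, and for each other list up to 4 bound genes of highest signal and up to 2 unbound genes, first in list order; outside promoters, the 5 strongest peaks. Alternatives changed the promoter distance (250 and 1000 bp), the TSS set, the summit (peak midpoint), the threshold (the 1390 peaks of highest signal), the random positions (weaker peaks in their place), the motif, window and flank, the overlap that counts as shared, the number of top peaks, the genome build and the definition of a bound gene. Leaving out each replicate in turn was planned for replicate support and signal. For the other results it was chosen after seeing the data, using peaks shared by the strongest lists of the remaining pair. The 6-mer scan within promoter and other peaks, the comparisons of motifs between them and the 8-mer scan were also chosen after seeing the data.

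The tests were tested on simulated data with planted effects. A planted 2-fold excess of positions was recovered as 1.99-fold and called in 100% of 100 runs, and 7% of runs without an effect were called. A motif planted in 10% of central windows was called in 100% of runs (2% without an effect), 9 of 10 planted 6-mers were called, and planted gene lists were called in 100% of runs (0.4% without an effect). Simulated central and flank windows were both drawn at random from the genome. They lacked the GC difference of the real windows (37.8% against 44.1%), so the motif and 6-mer rates do not cover errors from base composition. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.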

Results

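Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos of mixed sex, 0 to 24 h old, that carried Ets65A fused at its C-terminus to GFP. Ets65A is a transcription factor of the ETS family, whose members bind DNA through a domain that recognises a GGAA core. All libraries belonged to 1 group with 3 biological replicates, so the comparisons set bound positions against the genome, against their own flanks or against other genes, and each question follows from what was measured: where the tagged factor was found, at which sequences and near which genes. The values were peak lists, which hold no read counts, so the sequencing depth of each replicate is unknown here. The list of peaks that passed the authors' threshold of irreproducible discovery rate (IDR), called IDR peaks from here on, held 2780 peaks in the dm6 build and 3086 in the dm3 build. The pooled list, called on the 3 replicates' alignments together, held 28940 and 25994 peaks, and each replicate's own list held 30000. The 2780 dm6 IDR peaks were the 2780 pooled peaks of highest signal value, 9.61% of that list, with signal values from 71.8 to 1498 and a median of 110.2. All positions and comparisons below are in dm6 unless another build is named.

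Ets65A-eGFP peaks lay mostly at gene promoters. Of the 2780 IDR summits, 1642 (59.1%, 95% Wilson interval 57.2 to 60.9) were within 500 bp of a transcription start site (TSS) of a protein-coding gene, against 11.5% ± 0.603 (SD over 10000 sets) of random positions on the same chromosome arms, a 5.14-fold difference. The fold was 8.02 with promoters limited to 250 bp and 3.32 with 1000 bp, and 2.42 against weaker pooled peaks in place of random positions. Another 742 summits (26.7%, 25.1 to 28.4) were in introns and 313 (11.3%, 10.1 to 12.5) between genes, both shares being lower than the random 39.9% and 27.7%. Coding exons held 5 summits (0.180%, 0.0768 to 0.420) against 13.9% of random positions, 3' UTRs 17 (0.612%, 0.382 to 0.977) against 4.53%, and 5' UTRs outside promoters 12 (0.432%, 0.247 to 0.753) against 0.791%. The median distance to the nearest TSS was 241 bp, 910 summits (32.7%) were within 100 bp, and 357 (12.8%) were beyond 5000 bp.

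The promoter, coding exon, 3' UTR, intron and intergenic shares each differed from random at an adjusted p of 1.4e-04 (two-sided permutation test, Benjamini-Hochberg over 7 classes), which comes from an unadjusted p of 1e-04, the smallest that 10000 random sets can give. For 5' UTRs the adjusted p was 0.0449, and for other exons (49 summits, 1.76% against 1.60%) the test did not pass, at an adjusted p of 0.485. The 25669 weaker pooled peaks that overlapped no IDR peak were at promoters in 24.4% and in coding exons in 15.4% of cases. They run down to a -log10 q of 0.0177, so not all of them need be bound sites. Promoter shares among each replicate's own 2780 strongest peaks were 54.2%, 58.9% and 59.7% for replicates 1, 2 and 3.

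**Figure D1:**
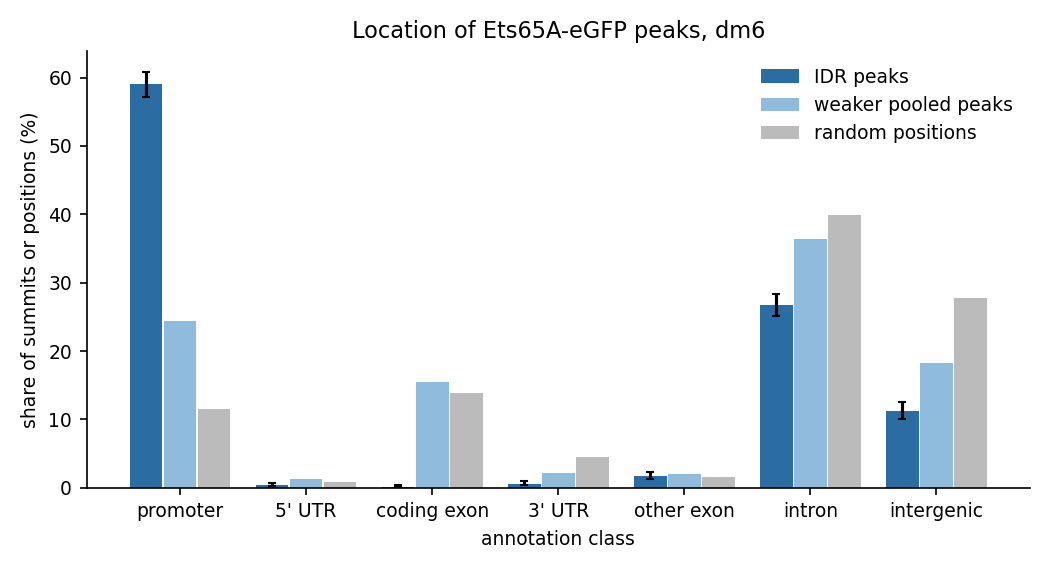
Share (%) of positions in each annotation class for the 2780 IDR summits (dark bars, with 95% Wilson intervals), the 25669 weaker pooled peaks (light bars) and random positions on the same arms (grey bars, mean of 10000 sets). Promoters held 59.1% of IDR summits against 24.4% of weaker peaks and 11.5% of random positions, while coding exons held 0.180%, 15.4% and 13.9%.

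The strongest promoter peaks lay at genes of varied function. The highest signal value, 1498, was at CG14100 (FBgn0036889, 3L, summit 19590633, 109 bp from the TSS, between genes), which ranked 1 in all 3 replicates. Ugalt, a UDP-galactose transporter (FBgn0024994, X, summit 2703891, between genes), had 1376. Chro, which encodes the chromatin and spindle protein Chromator (FBgn0044324, 3L, summit 22878869, in the 5' UTR), had 1066, with the TSS of Ssl1 also within 500 bp. Next came px, a gene of wing vein patterning (FBgn0003175, 2R, summit 22514297, in an intron), with 1057, and ph-p, a Polycomb group gene (FBgn0004861, X, summit 2137342, in an intron), with 1011. The ph-p summit was 487 bp from the TSS and was no longer a promoter peak at a distance limit of 250 bp. PNPase, a mitochondrial RNA-degrading enzyme (FBgn0039846, 3R, summit 31404664, in the 5' UTR), had 988.

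The rest of the 25 genes with the strongest promoter peaks had signal values from 549 to 821. They included mRpL41 (727) and mRpL23 (616, shared with CG9004) of the mitochondrial ribosome, RpS27 (663, shared with Nup37) of the cytoplasmic ribosome, the RNA-binding protein gene larp (699) and eIF6 (637), a factor of the large ribosomal subunit. The larp summit was 335 bp from the TSS, and its strongest promoter peak had a signal value of 127 at a limit of 250 bp. CenG1A (781) shared its peak with mRpS23 and Art3 (594), an arginine methyltransferase gene, shared its peak with mRpS10, both of the mitochondrial ribosome. The adaptor gene Shc (769.96) shared its peak with Atat, and Atf3 (549) encodes a bZIP transcription factor. The others were CG1888, CG7601 (shared with CIA30), CG9147 (Fbw5), CG31145, CG5098 (CG5757), Pal1 (Pdrg1), CG18549, GstE13, CG6966 and tank (CG12194).

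The 5 strongest peaks away from promoters were all in introns. The strongest was in ush, which encodes a cofactor of GATA factors (2L, 480889 to 481278, summit 481079), with a signal value of 1293, and its nearest TSS was that of cbt, 1391 bp away. The others were in CG11050 (2L, summit 6612709, 1069.6), in Lk6, a kinase gene (3R, summit 11761053, 912), in CG32772 (X, summit 4910375, 855) and in CG9663 (2L, summit 3302191, 724). Median signal values were 112 for promoter peaks and 107 for other IDR peaks, a log2 difference of 0.07 (two-sided permutation test over peaks, p = 0.021). With promoters limited to 250 bp the difference was 0.03 and did not pass (permutation p = 0.39), whereas with the mean signal of the replicates' own peaks it was 0.12 (permutation p = 2.7e-04), and between 0.08 and 0.14 with each replicate left out, passing each time. Peaks are not independent replicates.

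The ETS consensus was not more frequent at summits than in flank windows 500 bp away. The consensus CMGGAAR was within 100 bp of 223 summits (8.02%, 7.07 to 9.09) and in 244 flank windows of equal size centred 500 bp away (8.78%, 7.78 to 9.89), a ratio of 0.914 that did not pass the exact McNemar test (two-sided, p = 0.337, adjusted exact p = 0.466 over 18 motifs). Its core CCGGAA was in 5.61% of central and 6.40% of flank windows (ratio 0.876, adjusted exact p = 0.391), and the octamer CCGGAAGT in 20 and 12 windows (ratio 1.67, adjusted exact p = 0.388). Among each replicate's 2780 strongest peaks the shares of CMGGAAR were 8.06% central against 8.99% flank in replicate 1, 7.77% against 8.85% in replicate 2 and 8.74% against 8.31% in replicate 3. Central windows had a GC content of 37.8% and flank windows 44.1%. The direction depended on the comparison: against dinucleotide-shuffled central sequence the ratio was 1.33 (exact p = 0.0039) for the consensus, 1.47 for CCGGAA (adjusted exact p = 0.0037) and 2.86 for the octamer (adjusted exact p = 0.0265). Against flanks, the consensus ratio was 1.01 with windows of 50 bp each side (exact p = 1) and 0.841 with 200 bp each side (exact p = 0.0059). The consensus ratio was also above 1 in peaks outside promoters alone (1.11, exact p = 0.563). In bins of 50 bp, the consensus had 0.0223 and 0.0291 sites per peak just before and after the summit. It fell to 0.0147 at -100 to -51 bp and 0.0151 at 100 to 149 bp. This local rise was not tested, and the windows of 100 bp each side take in part of the drop.

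Core promoter elements, by contrast with the ETS site, were far more frequent at summits than in flanks. The DNA replication-related element (DRE, TATCGATA), bound by Dref, was in 162 central windows (5.83%, 5.02 to 6.76) and 17 flank windows (0.612%, 0.382 to 0.977), a ratio of 9.53 (adjusted exact p = 4.6e-30). The element bound by M1BP (GGTCACAC), common at promoters of housekeeping genes, was in 108 (3.88%, 3.23 to 4.67) and 16 (0.576%, 0.355 to 0.933), a ratio of 6.75 (adjusted exact p = 6.94e-18). Without replicate 1, in an alternative chosen after seeing the data, the M1BP shares came closer, at 3.28% and 1.03%. DRE was more frequent in the centre in 3 of 3 replicates, at 5.40%, 5.68% and 5.36% against 0.468%, 0.755% and 0.647%. Both elements were found mainly at promoter peaks: DRE in 9.62% of 1642 promoter peaks and 0.351% of 1138 other peaks (odds ratio 30.2, Fisher's exact test, adjusted exact p = 6.15e-31), and the M1BP element in 6.27% and 0.439% (odds ratio 15.2, adjusted exact p = 1.27e-17). At other peaks neither passed against flanks, with DRE in 4 central and 6 flank windows (exact p = 0.754) and the M1BP element in 5 and 2 (exact p = 0.453).

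Of the 15 fixed motifs outside the ETS family, 6 were more frequent and 2 less frequent in the centre. Besides DRE and the M1BP element, the TATA box (29.6% against 18.5%, ratio 1.60), the Mef2 site (10.4% against 6.08%, ratio 1.70), the homeobox site (14.6% against 11.1%, ratio 1.31) and the GATA site (25.9% against 21.1%, ratio 1.23) were more frequent. The Snail-class E-box CAGGTG (6.08% against 9.35%, ratio 0.650) and the CA repeat (14.3% against 19.9%, ratio 0.718) were less frequent. The adjusted p of these 6 ranged from 2.34e-20 for the TATA box to 2.43e-04 for the homeobox site. The sites of the GAGA factor, Zelda, AP-1, CRE, Sox, Runx and the E-box CAGCTG did not pass, with ratios from 0.882 to 1.10. GAGA sites were unevenly spread around summits, which the ratio of whole windows does not show. They had 0.0324 and 0.0363 sites per peak in the bins of 50 bp just before and after the summit. The highest bins were 0.0705 at -200 to -151 bp and 0.0723 at 100 to 149 bp. This profile was not tested. Against shuffled central sequence, the GATA site turned to less frequent (ratio 0.889, adjusted exact p = 0.0102), the CA repeat to more frequent (1.38, adjusted exact p = 1.62e-05) and CAGGTG to a ratio of 1.25 that did not pass (adjusted exact p = 0.0622), while the homeobox site no longer passed (1.01, adjusted exact p = 0.969) and the TATA box ratio was 1.15 (adjusted exact p = 0.0018). Also against shuffled sequence, the GAGA site (ratio 2.47, exact adjusted p = 4.87e-20) and CAGCTG (3.16, p = 1.1e-28) passed as more frequent, and Zelda (0.732, p = 0.0152) and Sox (0.892, p = 0.024) as less frequent. In peaks outside promoters, a split chosen for these motifs after seeing the data, CAGGTG turned to a ratio of 1.10 (exact p = 0.603) against 0.487 at promoter peaks, the homeobox (1.05) and Mef2 (1.33) sites did not pass, and CAGCTG was less frequent (0.615, adjusted exact p = 0.0103), against 1.24 at promoter peaks (adjusted exact p = 0.025). At promoter peaks the Sox site also passed (1.28, adjusted exact p = 6.48e-04). The TATA box was not tied to promoters. It passed against flanks in peaks outside them too (1.36, adjusted exact p = 4.82e-04), as did the GATA site (1.20, adjusted exact p = 0.0481). TATA box shares were 29.5% at promoter summits and 29.9% at other summits (odds ratio 0.981, Fisher's exact test, adjusted exact p = 0.937). In the 1390 peaks of highest signal, neither GATA (1.14, adjusted exact p = 0.108) nor homeobox (1.26, adjusted exact p = 0.0638) passed.

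**Figure D2:**
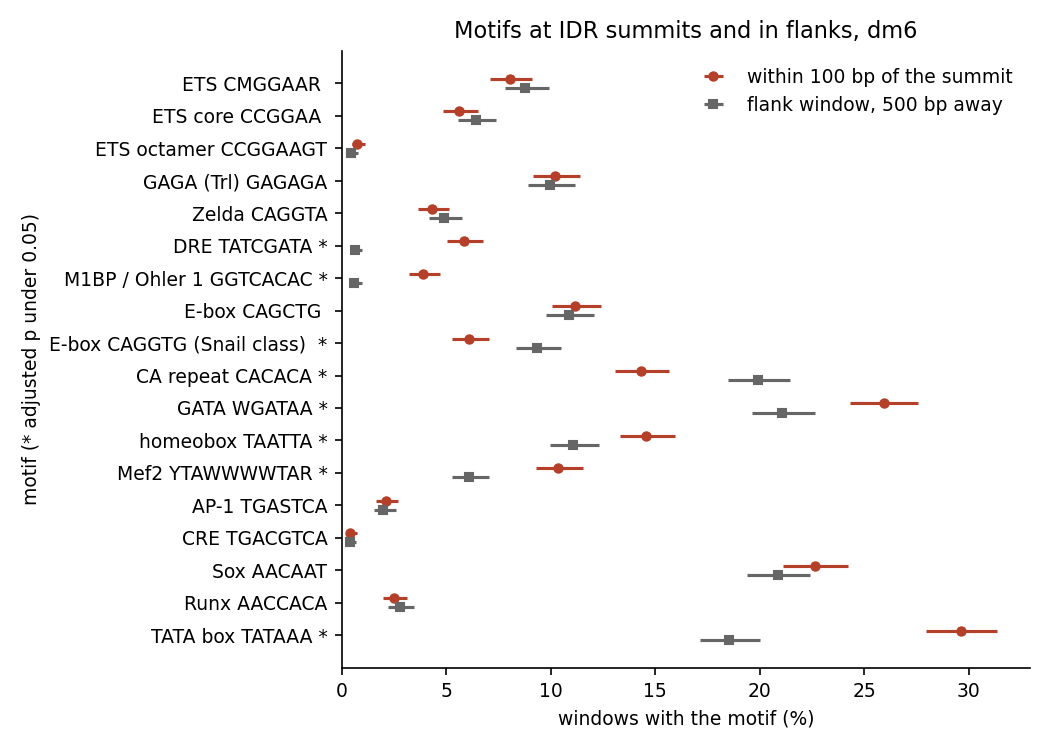
Share (%) of the 2780 IDR peaks with each of 18 fixed motifs within 100 bp of the summit (red) and in a flank window centred 500 bp away (grey), with 95% Wilson intervals; a star marks an adjusted p under 0.05. DRE (5.83% against 0.612%) and the M1BP element (3.88% against 0.576%) differ most by ratio, and the ETS consensus (8.02% against 8.78%) did not pass the test.

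**Figure D3:**
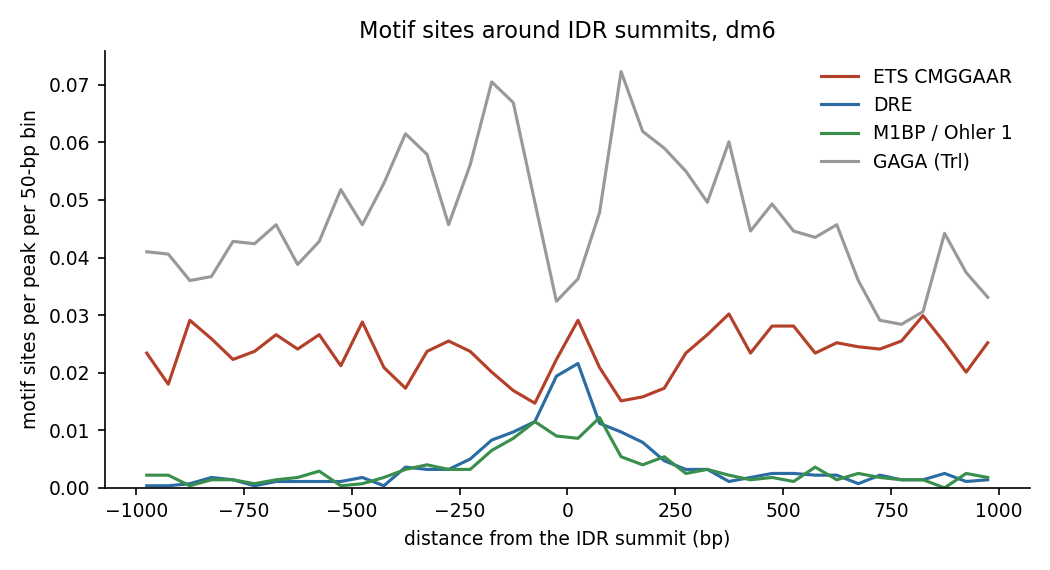
Motif sites per IDR peak in bins of 50 bp, by distance (bp) from the summit, for the ETS consensus, DRE, the M1BP element and the GAGA site. DRE reached 0.0216 sites per peak in the bin that starts at the summit. The ETS consensus had 0.0291 in that bin, 0.0223 in the bin just before it and up to 0.0302 away from the summit (350 to 399 bp). Between these it fell to 0.0147 (-100 to -51 bp) and 0.0151 (100 to 149 bp). The GAGA site had 0.0324 and 0.0363 in the bins just before and after the summit, and reached 0.0705 (-200 to -151 bp) and 0.0723 (100 to 149 bp).

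Of the 6-mers that passed in a scan of every 6-mer, CGATAG had the highest ratio of central to flank windows, followed by ACACTG and TATCGA. With each 6-mer and its reverse complement taken as 1, 498 were more frequent in central windows and 782 less frequent (exact McNemar test, Benjamini-Hochberg). Together these were most of the 6-mers tested. CGATAG, which overlaps DRE, was in 14.6% of central and 4.14% of flank windows (ratio 3.53), ACACTG in 23.1% and 7.66% (ratio 3.01), and TATCGA, the start of DRE, in 18.9% and 6.33% (ratio 2.99). The next were ACTAGT (2.72), CTAGTA (2.38), ACTATC (2.38), TAGCTA (2.28), AGTGTA (2.27), ATCGAT (2.26) and ACTGTA (2.19). Of these 10, 0 held GGAA. Central windows were poorer in GC than flanks (37.8% against 44.1%), and the scan was not run against shuffled sequence. How far base composition shaped these counts, or the lack of GGAA among the first 10, was therefore not tested. In the 1390 peaks of highest signal 395 6-mers were more frequent, CTAGTA had the highest ratio (3.44) and 5 of the 10 first 6-mers were shared.

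Genes of the cytoplasmic ribosome were the gene group with bound promoters far more often than other genes. An IDR summit was within 500 bp of a TSS of 58 of 88 cytoplasmic ribosomal protein genes (65.9%), against 15.5% of all other protein-coding genes (odds ratio 10.6, two-sided Fisher's exact test, adjusted exact p = 7.23e-25 over 21 lists). The highest signal values in the list were those of RpS27 (663), RpL7 (542), RpL23A (445) and RpL14 (403), while RpL10Aa and RpL12 were not bound. Random lists matched on TSS number held 16.3 bound genes on average (10 to 24), and the matched adjusted p was 0.0021, the smallest 10000 lists can give after adjustment over 21 lists (unadjusted 1e-04). Over the genome, 2200 of 13945 protein-coding genes (15.8%) had a bound promoter, and 706 of the 1642 promoter peaks (43.0%) lay within 500 bp of TSSs of more than 1 gene, so neighbouring genes were not counted independently. Genes in a list are not independent replicates.

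No other list passed in the main test. Other housekeeping groups were cell cycle and replication with 10 of 27 bound (37.0%, odds ratio 3.15, adjusted exact p = 0.0626), including Dp (174), BubR1 (155), dup (148) and RnrS (123) but neither CycB nor CycB3; proteasome subunits with 9 of 32 (28.1%, adjusted exact p = 0.458), including Rpn5 (219), Rpn6 (143), Rpn3 (125) and Prosalpha3 (116) but neither Prosalpha1 nor Prosalpha2; and RNA splicing with 7 of 25 (28.0%, adjusted exact p = 0.458), including SNRPG (169), SF2 (137), U2af50 (101) and B52 (86.5) but neither U2af38 nor snRNP-U1-70K. Oxidative phosphorylation had 15 of 84 bound (17.9%, adjusted exact p = 0.738), including ND-ASHI (239.8), ND-MWFE (234), ND-51 (198) and COX5B (176) but neither ATPsynB nor ATPsynC.

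In the nervous system lists, 1 of 26 pan-neuronal genes was bound (3.85%, adjusted exact p = 0.458), namely elav (X, summit 523478, 252 bp from the TSS, signal value 304), while nSyb and Syt1 were not. Random lists matched to the pan-neuronal one on TSS number held 6.42 bound genes on average (3 to 11), with a matched p of 0.0166 (adjusted 0.116). Of 21 neuroblast genes 2 were bound, numb (155) and brat (73.4, or 217 within 1000 bp), and ase and dpn were not (adjusted exact p = 0.738). Of 13 glial genes 3 were bound, moody (305), loco (88.9) and nrv2 (82.0), and repo and gcm were not (adjusted exact p = 0.689). Of 30 axon guidance genes 6 were bound (adjusted exact p = 0.689), including Abl (155), unc-5 (112), dock (106) and PlexA (97.3), and robo1 and robo3 were not. When a summit anywhere in the gene body or within 1000 bp of it was counted, axon guidance had 16 of 30 (odds ratio 3.84, adjusted exact p = 0.0021) and EGFR and FGF signalling 15 of 27 (odds ratio 4.20, adjusted exact p = 0.0021), so that 3 lists passed; this count was not matched on gene length.

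The remaining lists, of other tissues and of signalling pathways, did not pass either. Bound mesoderm and muscle genes were 4 of 28 (adjusted exact p = 1), namely sls (253), mbc (155), Mef2 (95.7) and htl (94.2) but not twi or tin. Bound germ line genes were 4 of 14 (adjusted exact p = 0.602), namely bgcn (219.5), orb (132), nanos (119) and Sxl (96.3) but not vas or osk. EGFR and FGF signalling had 7 of 27 (adjusted exact p = 0.539), including spi (338), Ras85D (137), htl and csw (76.8) but not Egfr or vn. Segmentation had 2 of 24 (adjusted exact p = 0.689), bcd (176) and nkd (135) but not hb or Kr. Ecdysone response had 2 of 14 (adjusted exact p = 1), Eip75B (183) and usp (119.9) but not EcR or br. Notch signalling had 2 of 20 (adjusted exact p = 0.838), E(spl)m7-HLH (79.1) and mib1 (71.8) but not N or Delta. Endoderm and gut had 2 of 10 (adjusted exact p = 0.774), bowl (137) and fkh (122) but not srp or hkb. Hemocyte and blood had 1 of 18 (adjusted exact p = 0.689), ush (80.8), but not srp or lz. Trachea had 0 of 13 (adjusted exact p = 0.602, trh and btl among them), epidermis and cuticle 0 of 14 (adjusted exact p = 0.513, grh and shg among them) and the Hox genes 0 of 8 (adjusted exact p = 0.767, lab and pb among them). These lists were too short for even 0 bound genes to pass, with unadjusted Fisher's exact p of 0.243, 0.147 and 0.62. Random lists matched to epidermis and cuticle on TSS number held 3.04 bound genes on average (0 to 6), with a matched p of 0.0408 (adjusted 0.214). At a limit of 250 bp, elav, nrv2, sls, htl, orb, nanos, Sxl, E(spl)m7-HLH, ND-ASHI, COX5B and SNRPG no longer counted as bound, and at 1000 bp vas did. Among the bound genes named, the peaks at nrv2 and ush had no counterpart in the whole list of replicate 1, and that at Sxl had none in replicate 2.

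Of the 8 ETS family genes 2 had a bound promoter (adjusted exact p = 0.689). These were pnt (FBgn0003118, 3R, summit 23314564, 249 bp from a TSS, signal value 86.6) and aop (FBgn0000097, 2L, summit 2178787, 33 bp, 73.9), an activator and a repressor that act downstream of receptor tyrosine kinases. Both peaks were weak, at ranks 2084 and 2650 among the IDR peaks. In replicates 1, 2 and 3 the pnt peak ranked 2834, 4495 and 838, and the aop peak 2663, 13621 and 1636. Ets65A itself (FBgn0005658, 3L, 6097617 to 6123913, plus strand) was not bound at a promoter. The IDR summit nearest to one of its TSSs, at 6094932, was 2685 bp away with a signal value of 273. When summits in the gene body or within 1000 bp of it were counted, Ets65A was bound, by a different IDR summit. The summit nearest to Ets96B was 608 bp from its TSS (237) and counted as bound at a limit of 1000 bp. The summits nearest to the other four genes, Eip74EF, Ets21C, Ets98B and Ets97D, were 2291, 21521, 29613 and 31324 bp away.

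**Figure D4:**
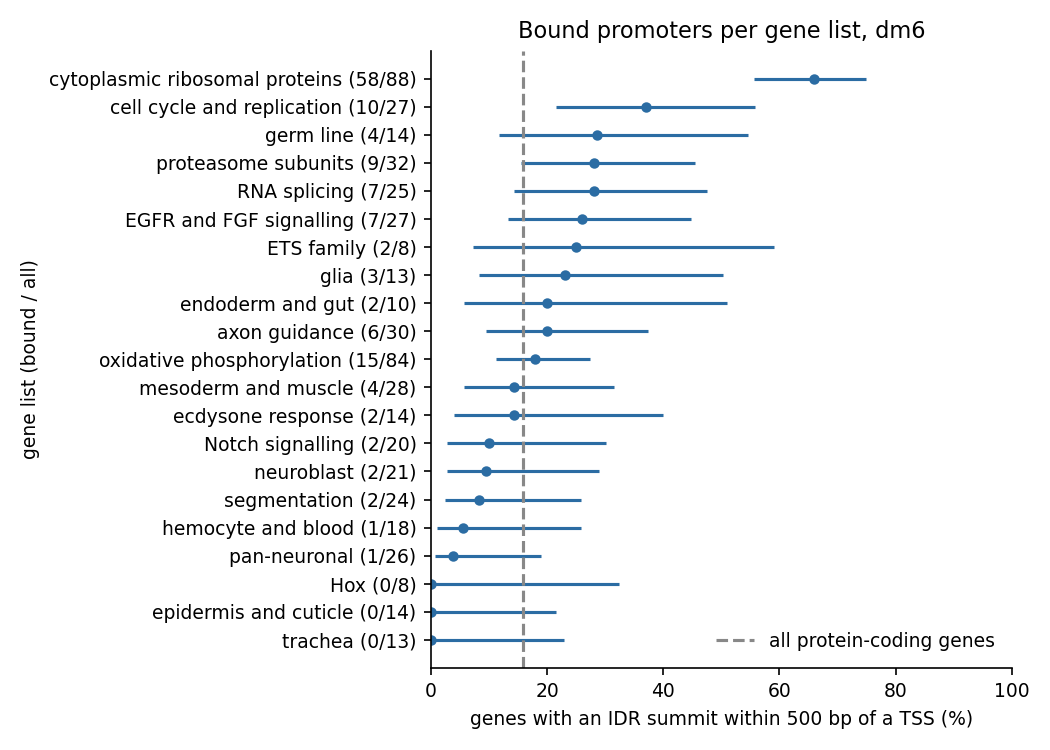
Share (%) of genes in each of 21 fixed lists with an IDR summit within 500 bp of a TSS, with 95% Wilson intervals and the bound and total numbers of genes; the dashed line is the share of all protein-coding genes, 15.8%. Cytoplasmic ribosomal protein genes (58 of 88) lie farthest above the line, and the lists for Hox genes, epidermis and cuticle, and trachea are at 0.

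The replicates shared most of their strongest peaks. Of each replicate's 2780 strongest peaks, 70.8% were shared between replicates 1 and 2, 64.7% between 1 and 3 and 73.6% between 2 and 3 (mean of both directions), with a mean of 69.7% ± 4.54 (SD, n = 3 pairs). Lists shifted along the arms shared 2.23% at most, so that no shift reached the overlap of any pair (permutation test, p = 0.0099, the smallest that 100 shifts can give). Of the IDR peaks, 1650 (59.4%) were among the strongest of all 3 replicates, 767 of 2, 348 of 1 and 15 of 0. Across IDR peaks found in both lists, Spearman's rho of the signal values was 0.694, 0.572 and 0.665 for the pairs 1 and 2, 1 and 3, and 2 and 3; this is across peaks, which are not independent replicates, and not across samples.

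Replicate 1 stood apart in where its peaks lay. Coding exons held 67 of its 2780 strongest peaks (2.41%) against 4 and 6 in replicates 2 and 3, and 19.0% of its whole list was at promoters against 28.5% and 30.8%. Of its strongest peaks, 103 were in neither other replicate's whole list, 32 of them in coding exons, against 4 and 20 such peaks in replicates 2 and 3. In peaks shared by the strongest lists of the remaining pair, an alternative chosen after seeing the data, leaving out replicate 1 gave a promoter share of 59.9% (5.20-fold), a DRE ratio of 8.33, 53 of 88 ribosomal protein genes bound and 1636 bound genes, 1607 of them among the 2200. Without replicates 2 and 3 the promoter fold was 5.30 and 5.23, the DRE ratio 9.09 and 6.94, the M1BP element was in 3.24% against 0.614% and 3.05% against 0.509% of windows, and 48 and 53 ribosomal protein genes were bound. The number of bound genes fell to 1494 without replicate 2, where 1792 peaks were left.

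IDR peaks were spread over all 6 chromosome arms, with chromosome 4 the lowest. Per Mb, there were 21.5 (exact 95% Poisson interval 19.6 to 23.4) on X, 22.2 (20.3 to 24.1) on 2L, 20.6 (18.9 to 22.5) on 2R, 19.5 (17.9 to 21.2) on 3L, 21.1 (19.5 to 22.7) on 3R and 9.01 (4.66 to 15.7) on chromosome 4, which held 12 peaks. The arms differed from an even rate (chi-square 13.9, 5 degrees of freedom, p = 0.0162), and the rate on X was 1.03 times that of chromosomes 2 and 3 together. Among the 1390 peaks of highest signal the chi-square test did not pass (p = 0.175). Bound promoters made up 13.2% of the genes on X and 6.25% of those on chromosome 4, against 15.3% to 17.8% on the other arms.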

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

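The strongest 556 peaks and the leave-out settings other than those of replicate support and signal were chosen after seeing the data; the other alternatives were planned. Of the alternatives for results that answer a comparison, 56 kept their direction and their side of the threshold, or their value within the spread or, for counts, within a set factor. Counts within that factor still moved. Bound genes ran from 1494 (without replicate 2) to 2503 (within 1000 bp), against 2200. IDR peaks among the strongest of every replicate ran from 1290 (overlap of at least 50% of both peaks) to 2001 (without replicate 1), against 1650. The ETS ratio of 0.914 turned to 1.67 with the octamer (exact p = 0.215), 1.01 with 50 bp each side (exact p = 1), 1.33 against shuffled sequence (exact p = 0.0039), 1.11 in peaks outside promoters (exact p = 0.563) and 1.38 in the strongest 556 peaks (exact p = 0.115), and passed with 200 bp each side (0.841, exact p = 0.0059). Against shuffled sequence, the GATA ratio turned to 0.889 and that of the CA repeat to 1.38; the shuffle keeps the base composition of the summits, and no other cause of these changes was tested. The 1390 peaks of highest signal, being fewer, gave 1202 bound genes, and an X ratio of 1.06 whose arm test no longer passed. Counting summits in gene bodies gave 3 lists. Mean replicate overlap was 64.1% when an overlap of at least 50% of both peaks was required and 58.9% with 2 times as many top peaks; leaving out a replicate left pairs at 64.7% to 73.6%. The promoter signal difference (log2) was 0.0254 at 250 bp (permutation p = 0.39). The causes of these shifts were not tested. Of 105 alternatives for single lists 103 gave the same call, of 30 for single motifs 20, and of 363 for named genes 333. The arm rates in dm3 were not run. Depth is unknown from peak lists, so no limit from it could be given.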

Other observations

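Of the tests in this part, those of DRE and the M1BP element against promoter location and of the ETS site against base composition were set before their results were seen. The comparison of DRE with shuffled sequence was also fixed beforehand, though its use to weigh base composition came after its value was seen, and unless stated the other tests were chosen after. Peaks at promoters and elsewhere differed in the short sequences at their summits. At 1642 promoter peaks, 8-mers that overlap DRE came first by p, followed by CAACACTG, present in 8.89% of central and 0.609% of flank windows (146 against 10 peaks, exact McNemar test, adjusted exact p = 3.39e-28). At 1138 other peaks, CACTGAGA came first (6.59% against 0.527%, 75 against 6 peaks, adjusted exact p = 1.27e-12), then TACACTGA (5.54% against 0.527%) and GAGAGAAA (7.38% against 1.58%). The 6-mer ACACTG was more frequent at the centre of both, at 24.6% against 7.49% of promoter peaks and 20.8% against 7.91% of other peaks. The E-box CAGCTG was more frequent at promoter summits than at other summits (246 of 1642 against 64 of 1138 peaks, odds ratio 2.96, Fisher's exact test, adjusted exact p = 1.08e-14), with 12.1% and 9.14% in their flanks. The GAGA site was less frequent at promoter peaks than at other peaks both at the summit (7.61% against 14.0%) and in the flank (7.73% against 13.2%).

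Genes for tRNAs, snoRNAs, rRNAs and other non-coding RNAs (ncRNA) were bound less often than protein-coding genes, of which 15.8% had a summit within 500 bp. The shares were 3.45% of 290 tRNA genes (adjusted exact p = 9.68e-11), 3.72% of 269 snoRNA genes (adjusted exact p = 1.24e-09), 0 of 99 rRNA genes (adjusted exact p = 9.75e-08) and 4.02% of 3261 ncRNA genes (adjusted exact p = 2.39e-86), all by Fisher's exact test. Many tRNA and rRNA genes have near-identical copies, and how reads that map to several places were handled is not given in the sources used here. Of 32 snRNA genes 6 were bound (18.8%, adjusted exact p = 0.627), and 5 of these 6 lay over 1000 bp from a protein-coding TSS. The TATA box, though more frequent at summits than in flanks, was in fewer bound than unbound promoters, taken within 500 bp of each gene's most upstream TSS (70.3% against 75.2%, odds ratio 0.780, adjusted exact p = 2.01e-05). The 556 strongest IDR peaks held the ETS core CCGGAA at the summit more often than the other 2224 (8.99% against 4.77%, and 3.96% to 5.76% in the other sets of 556, odds ratio 1.97, adjusted exact p = 0.0049), also CMGGAAR (11.2% against 7.24%, odds ratio 1.61, adjusted exact p = 0.0229), and the M1BP element less often (1.80% against 4.41%, odds ratio 0.397, adjusted exact p = 0.0229).

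DRE and the M1BP element were frequent at summits, and no biological explanation was tested for want of a second group. The base composition of the windows was argued against as the whole cause for DRE, which was 16.2 times as frequent as in shuffled sequence (adjusted exact p = 2.44e-37). Promoter location as the whole cause was also argued against, since bound promoters held DRE more often than unbound ones (22.4% against 10.6%, odds ratio 2.43, 95% interval 2.16 to 2.74), and the M1BP element likewise (17.6% against 9.83%, odds ratio 1.96, 1.72 to 2.23). Promoters in these comparisons lay within 500 bp of each gene's most upstream TSS (1990 bound, 11954 unbound), so unbound ones can belong to genes bound at another TSS. Promoters with a weaker peak alone held DRE less often than bound ones (17.2%, odds ratio 1.39, 1.22 to 1.58) but the M1BP element in 16.4% (odds ratio 1.09, 0.950 to 1.25), so the M1BP excess may be that of any promoter that gives a peak. For DRE this stays undecided. Weaker peaks run down to a -log10 q of 0.0177, so they can include unbound promoters, and promoters without a peak held DRE in 5.72%. Among IDR peaks, DRE was not more frequent in the strongest 556 than in the other 2224 (4.86% against 6.07%). Whether proteins bound at these elements, or open chromatin there, bring the tagged factor or the signal to them was not tested.

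The ETS consensus was not more frequent at summits than in flanks, although the factor has an ETS domain and bound promoters held the core CCGGAA more often than unbound ones (34.8% against 31.1%, odds ratio 1.18, 1.07 to 1.31) and than those with a weaker peak (odds ratio 1.20, 1.08 to 1.34), with 1.09 (0.992 to 1.20) for the consensus against unbound promoters. The octamer CCGGAAGT did not differ between bound and unbound promoters (2.06% against 2.07%, odds ratio 0.997, 0.714 to 1.39). The CCGGAA excess was not particular to the ETS site. CAGCTG (odds ratio 1.53), the Sox site (1.26) and the CA repeat (1.23) exceeded it, as did DRE and the M1BP element. Of the motifs that passed, only the TATA box went the other way (0.780). The base composition of these promoters was not compared. A candidate explanation for the lack of an excess over flanks is base composition, since summits were poorer in GC: the consensus was 1.26 times as frequent as in the mean of 10 shuffles at the centre (95% interval 1.10 to 1.42) and 1.03 times in the flank (0.902 to 1.16), a ratio of ratios of 1.22 (1.01 to 1.47). That the many weaker peaks hide a site present in the strongest ones remains open, because the ratio in the 556 strongest was 1.38 without passing (11.2% against 8.09%, exact p = 0.115; CCGGAA 1.52, exact p = 0.0712), although it exceeded that of the other peaks, 0.809, by a ratio of 1.70 (95% interval 1.11 to 2.65). The ratio did not fall steadily with signal, being 0.647 (exact p = 0.0535), 0.793, 1.02 and 0.787 in the next sets of 556 peaks, and it was 0.849 (exact p = 0.212) in the 1390 peaks of highest signal, a comparison fixed beforehand in which the octamer was in 11 central and 2 flank windows (adjusted exact p = 0.0578). Binding without a site, or through other proteins, was not tested.

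Of 13331 windows of 100 kb, the one with most replicate 1 peaks (3L, 6100001 to 6200000, 55 peaks against a median of 24) overlapped Ets65A, as 0.0975% of windows do, with 13 of its peaks inside the gene and 42 beside it. Among windows with a like number of TSSs, 0.432% held as many replicate 1 peaks as the window centred on the gene (44 peaks), 45.6% as many replicate 2 peaks and 35.2% as many replicate 3 peaks. A region rich in genes stays open, because the replicate 1 value was measured where replicate 1 itself was densest. Extra copies of the region on the tagged transgene could raise the signal there and stay open too, because replicates 2 and 3 differ: the block was among the densest 4.75% of all windows in replicate 2 (46 peaks; 12.3% of windows with a like number of TSSs) and 14.9% in replicate 3 (40 peaks; 39.3%). The 3 replicates are labelled as the same strain, and read depth over the region was not analysed here.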
